A study of Mus musculus with 10 samples.

How the data were processed

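The samples were 10 centi-pools of mouse T cells, each hybridised with a common reference RNA on 1 two-colour array. Per the labels, RNA was amplified to antisense RNA, pools were labelled with Cy5 and the reference with Cy3. Images were read with Agilent Feature Extraction, per the submitters' processing notes, with no version given. The data used here are the value table of the series, 1 number per feature and array. The authors deposited these numbers without a stated base, centring or direction: they are signed, reach 7.38 in size, and have array medians from 0.005 to 0.131, so they are log ratios, and they were taken as log2 ratios deposited by the authors. A size of 7.38 is beyond what a scanner ratio reaches in log10 units, whereas a natural logarithm cannot be ruled out from the values, and therefore no fold changes are given. A minimum size of 1 unit and every size below are on the scale of the table. The ratio is likely pool over reference, since the pool is both the Cy5 and the first channel. Background correction, normalization and the reason for empty cells are not given in the sources used here. Signal intensities were not used here, so precision can be judged only from the number of arrays and the spread between them.

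The table held 15868 features, each with at least 2 values. Feature numbers matched 0 identifiers of the reference gene table for mouse (GRCm38.p6), so no feature could be given a gene name or a position. The files do not pair the numbers with genes. The design had foreseen averaging the probes of a gene, tests of 25 gene lists (16 of pathways and T cell states, 9 of cell type markers) and named genes. In their place each feature was tested on its own, and at most 2 features in each direction are given per comparison, those with the smallest p or, for the reference, the largest mean among called features with 1 sign on every array. For the spread between pools, the 2 features with the largest SD are given.

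Pools were grouped from the trait value in the labels, before the data were examined: under 2 (4 pools) and over 5 (6 pools). No label names these classes. Replicate numbers within a group follow the order of accession and pair nothing. No 2 arrays were alike: the SD of the difference between arrays was at least 0.54, and at most 12 of 10472 features had identical values in a pair.

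Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg) on the 12271 features with a value on at least 8 arrays, without further normalization. The 3597 other features were not tested in the main fits. The fits were a slope on log2(trait value + 1) over the 10 pools, the difference between the 6 higher and 4 lower pools, and the mean log ratio against 0 with a minimum size of 1 unit. Adjusted p-values under 0.05 were called. Correlations over pools are Pearson's r and Spearman's rho with two-sided permutation p-values, from 100000 resamples for 10 pools and from every ordering for fewer, and 12 relations with the trait formed 1 family for adjustment. Principal components were computed on the 10472 features with a value on all arrays, centred per feature. The 5% of these with the largest SD were clustered by average linkage on 1 minus their correlation and divided into 6 groups.

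The fits were tested on simulated data. With the real pools reassigned at random and known changes added to 200 of 12271 features in 20 draws, the slope recovered 18.6% of changes of 2 units over the trait range, with 1.75 false calls per draw, and 90.95% of changes of 4 units, with 15.9 false calls per draw. The group difference recovered 0.35% of changes of 1 unit, 71.05% of changes of 2 units and 99.28% of changes of 4 units, with 0.95, 7.45 and 12.35 false calls per draw. Every recovered change had the right sign.

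The alternatives were the scale of the trait, median centring, quantile normalization, other minimum numbers of values, a filter on the SD, trended and robust variances (statmod 1.5.0), array weights, the letter that begins a pool's name as a covariate, another division of the pools, and leaving out each pool in turn. Alternatives added after the data were seen were the 8 P pools alone, the leading 2 letters of the name as a random block, those for missing values, and other numbers of feature groups.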

Results

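Expression was measured on 10 two-colour Agilent arrays, each of which held RNA from 1 centi-pool of mouse T cells in the Cy5 channel and a common reference RNA in the Cy3 channel. A centi-pool is a population grown in culture from a small, fixed number of sorted cells, here polyclonal Vbeta3+, TCRalpha+/- T cells from B10.A mice positive for pigeon cytochrome c (PCC). The pools had been screened for "deletor" activity against 5C.C7 T cells, which carry a PCC-specific receptor, by counting the 5C.C7 cells left in recipient mice. The reference was a mixture of naive, memory and tolerant T cell RNA in equal parts from 5C.C7 mice without RAG2.

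The labels give each pool a number for the deletor trait, from 0.02 in pool PB5 to 29.97 in pool PD5. They give no unit, and they do not say whether a larger number stands for more deletor activity or for less, so every result below is stated by trait value alone. The lower group held 4 pools with trait values under 2 (PB5 at 0.02, SA1 at 0.80, PA1 at 1.17 and PA3 at 1.73). The higher group held 6 pools with trait values over 5 (PC3 at 5.25, PD4 at 6.97, PB4 at 10.60, PD3 at 19.40, SA2 at 22.60 and PD5 at 29.97). Each pool was hybridised once, so the spread within a group joins differences between pools with technical error. Of 15868 features in the table, between 12547 (SA2) and 14017 (PB5) had a value on an array, and 10472 had a value on all 10. Log ratios of different pools correlated with r between 0.459 and 0.891 across these 10472 features, which are not independent replicates, and with a median of 0.763 over the 45 pairs of arrays. Features are known here only by number. No gene is therefore named, and the lists of T cell subset, signalling and cell type marker genes fixed before the data were examined could not be tested.

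The first question was which features followed the trait value over the 10 pools. None of the 12271 features tested passed an adjusted p of 0.05 for a slope on log2(trait value + 1) (limma, Benjamini-Hochberg), and the lowest adjusted p was 0.14. At an unadjusted p under 0.05 there were 1184 features, 9.65% of those tested, of which 522 had positive and 662 negative slopes. Features vary together, so the 5% expected of independent features is no measure of chance here. Without PB5, the pool with the lowest trait value, this count was 741. The mean log ratio of an array itself tended to be lower at higher trait values, with r = -0.56 (permutation p = 0.051, adjusted p = 0.30 over 12 relations) and rho = -0.71 (permutation p = 0.026). Without PB5 and PD5, the pools farthest from the median of log2(trait value + 1), r was -0.68 (exact permutation p = 0.017). That set still held SA2, whose mean log ratio of -0.35 was the lowest. Within the 8 pools whose names begin with P, which leave out SA2 and SA1, r was -0.56 (exact permutation p = 0.15), with rho = -0.52 (exact permutation p = 0.20). How much of the excess of negative slopes goes with this shift was not tested. A positive log ratio likely means more RNA in the pool than in the reference, since the pool was in Cy5 and in the first channel, but the direction, like the base of the logarithm, is not stated with the values.

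The smallest p among positive slopes belonged to feature 6658029_1, whose log ratio was -2.47 ± 0.42 (SD, n = 4) in the lower pools and -0.95 ± 0.40 (SD, n = 6) in the higher pools. Its slope was 0.48 ± 0.07 (SE) per unit of log2(trait value + 1), with an adjusted p of 0.14. Feature 6684687_1 had a slope of 0.50 ± 0.08 (SE), with the same adjusted p of 0.14, and ran from -2.53 in PB5 to -0.08 in PD5. Among negative slopes, feature 6686349_1 had -0.58 ± 0.11 (SE, adjusted p = 0.34) and was measured on 8 arrays, with means of 1.07 ± 1.14 (SD, n = 3) in the lower and -0.46 ± 0.51 (SD, n = 5) in the higher pools. Feature 6678130_1 had -0.39 ± 0.08 (SE, adjusted p = 0.41) and was measured on 9 arrays. When each array was weighted by its own agreement with the fit, a processing alternative that gave SA2 a weight of 0.21 and PA3 a weight of 0.40, 3 features passed, among them 6658029_1 and 6684687_1, both with an adjusted p of 0.038. Over 23 alternatives the adjusted p of 6658029_1 ranged from 0.038 to 0.69 and that of 6684687_1 from 0.038 to 0.68.

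**Figure D1:**
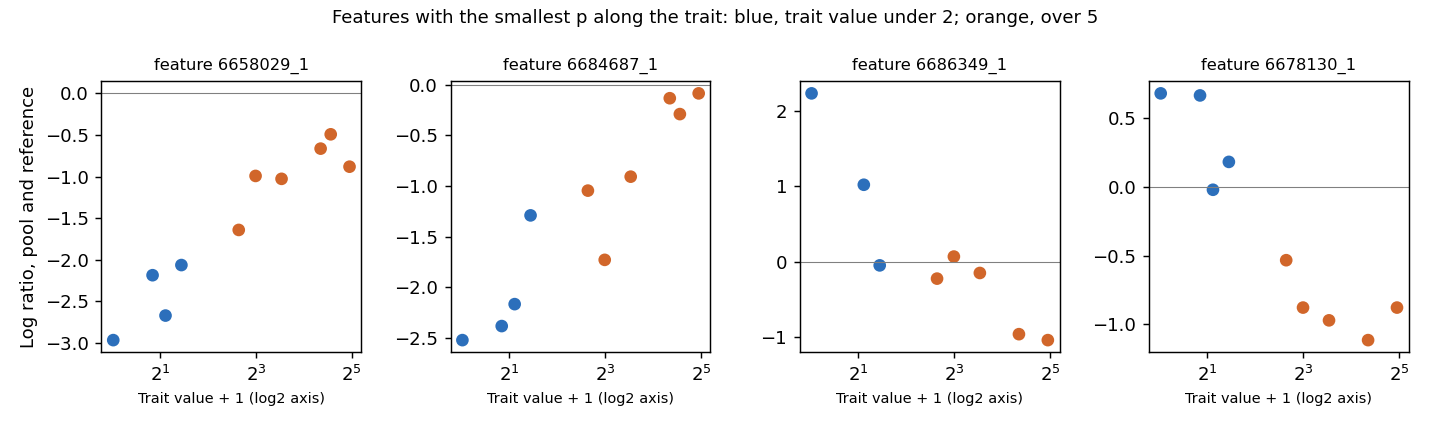
Log ratio of pool and reference (y axis) against trait value + 1 (x axis, log2 scale) for the 2 features with the smallest p among positive slopes and the 2 among negative slopes; each point is 1 pool, blue for trait values under 2 and orange for trait values over 5. Feature 6658029_1 lay between -2.97 in PB5 and -0.49 in SA2, and none of the 4 slopes passed the adjusted threshold.

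The precision of these slopes sets what could be seen. The median 95% half-width of a slope was 0.22 log ratio units per unit of log2(trait value + 1). In arrays reassigned at random with known changes added to 200 features, a change of 1 unit over the whole range of the trait was never recovered, a change of 2 units was recovered for 18.6% of the features, and a change of 4 units for 90.95%. Slopes that add up to 1 or 2 units over the range were thus largely not detectable with 10 arrays.

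The second comparison set the 6 higher pools against the 4 lower pools, since the series text describes pools at the ends of the activity range. No feature passed an adjusted p of 0.05 (limma), with a lowest adjusted p of 0.25, and 1167 features had an unadjusted p under 0.05, 462 with higher and 705 with lower log ratios in the higher pools. Feature 6648172_1 averaged 0.75 ± 0.18 (SD, n = 6) in the higher and -0.85 ± 0.46 (SD, n = 4) in the lower pools, a difference of 1.60 ± 0.25 (SE) with an adjusted p of 0.25. Feature 6669258_1 differed by 1.62 ± 0.27 (SE), also with an adjusted p of 0.25. In the other direction, feature 6660349_1 had a difference of -1.32 ± 0.25 (SE) and 6678130_1 one of -1.25 ± 0.25 (SE), each with an adjusted p of 0.38. With the pools over 15 set against all others, these differences were smaller, at 0.96 for 6648172_1, 1.09 for 6669258_1, -0.71 for 6660349_1 and -0.87 for 6678130_1. The 4 lower pools lay between -1.21 and -0.17 for 6648172_1 and the 6 higher pools between 0.53 and 0.97. With array weights 13 features passed, 12 of them higher in the higher pools, and over 21 alternatives the adjusted p of 6648172_1 ranged from 0.0051 to 0.72. The median 95% half-width of a difference was 0.73, and added differences of 2 units were recovered for 71.05% of features. The features at an unadjusted p under 0.05 in this comparison and in the slope shared 758 members, all with the same sign, as the predictors overlap by construction.

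Features differed widely in how much they varied between pools. Over the 10472 features with a value on all arrays, the median SD between pools was 0.54 and the highest was 2.30, for feature 6684819_1, which ran from -4.79 in SA2 to 2.91 in PD3. Feature 6676022_1, with an SD of 2.22, ran from -3.22 in SA2 to 2.60 in PA1. The 5% of features with the largest SD (1.15 and above) were divided by their profile over the pools into 6 groups, a division chosen after the data were seen. Features were placed together because they correlated, so a like profile within a group follows from how the groups were made. The largest, of 235 features, lay -2.79 below its own mean in SA2 and between -0.43 and 0.62 in the other pools. A group of 55 features lay 2.20 above its mean in SA2 and was lowest in PB5 (-1.11). A group of 173 features was low in PD4 (-1.52) and PD3 (-1.50) and high in PB4 (1.01), PB5 (0.99) and PA3 (0.82). A group of 42 features was lowest in PB5 (-2.05) and highest in PD4 (0.92) and PD3 (0.91). A group of 14 features was high in PD5 (1.31), SA2 (1.14) and PB5 (1.03) and low in PA3 (-1.59), PA1 (-1.13) and PB4 (-1.02). The smallest, of 5 features, was high in PA3 (1.52) and PD3 (1.27) and low in PD5 (-1.38).

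**Figure D2:**
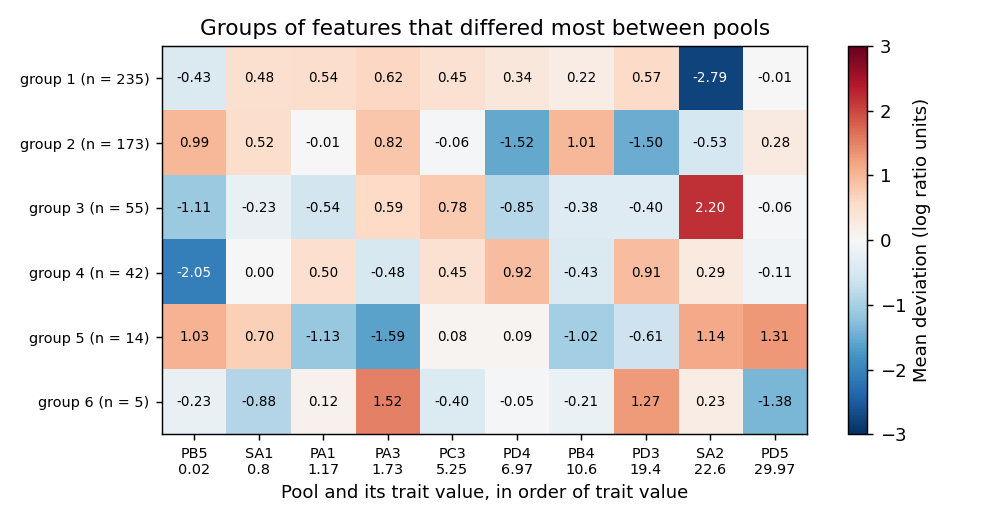
Mean deviation of each of 6 groups of features (rows, with the number of features n) from their own mean over the pools, in log ratio units, by pool (columns, in order of trait value, which is printed under each pool). The largest deviations are -2.79 and 2.20 in SA2, -2.05 in PB5, -1.59 in PA3 for the group of 14 features, and, for the group of 173 features, -1.52 in PD4.

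None of these groups followed the trait past the threshold. Over 12 relations with the trait that were computed together, the lowest adjusted p of a group mean was 0.37, with Pearson's r between -0.49 and 0.52 and unadjusted permutation p-values from 0.12 to 0.90. Without PB5 and PD5, r went from -0.34 to -0.56 (exact permutation p = 0.044, not adjusted) for the group of 235 features, and from 0.52 to 0.32 (exact permutation p = 0.41) for the group of 42 features. In the other 4 groups r without these pools lay between -0.52 and 0.34, with exact permutation p-values from 0.19 to 0.56. Among the pools left, SA2 had the highest trait value and held the group of 235 features at -2.79. Among the other pools that group was lowest in PB5 (-0.43) and then PD5 (-0.005), the pools with the lowest and highest trait values, and highest in PA3 (0.62). No relation of a group mean was computed without SA2, so the change in r of that group was not parted from this 1 array.

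The first principal component held 32.3% of the variance and separated SA2, with a score of 108.6, from the other 9 pools, whose scores lay between -20.5 and -0.95. The second held 19.4% and ran from -40.4 in PD4 and -35.4 in PD3 to 67.4 in PA3. The first component correlated with log2(trait value + 1) at r = 0.48 (permutation p = 0.13, adjusted p = 0.37) and rho = 0.71 (permutation p = 0.025). Without PB5 and PD5, the pools farthest from the median of log2(trait value + 1), r was 0.56 (exact permutation p = 0.032), with SA2 still among the pools. With SA2 alone left out and the components computed anew from the other 9 pools, r was 0.46 in size (permutation p = 0.21). That component is another axis, so this r cannot be set against the other values given here. For the scores on the component of all pools, within the 8 pools whose names begin with P, r was 0.71 (exact permutation p = 0.046) and rho 0.62 (exact permutation p = 0.12). The relation within the P pools was weaker without PB5 and PD5, with r = 0.42 (exact permutation p = 0.39). No other pair of pools was left out there for comparison. The 2 pools whose names begin with S were too few for a value.

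**Figure D3:**
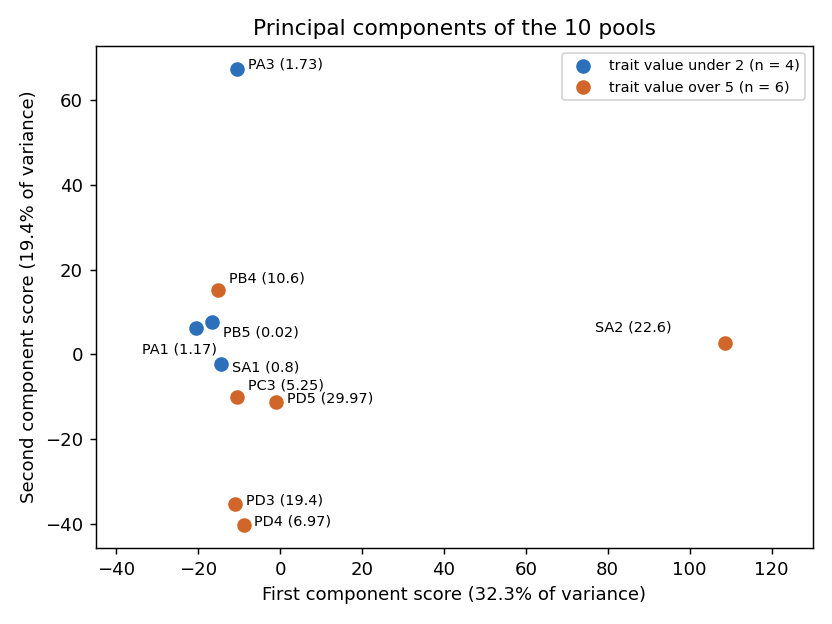
Scores of the 10 pools on the first component (x axis) and the second component (y axis) of 10472 features, with the share of variance of each; points are pools, named with their trait value, blue for trait values under 2 and orange for trait values over 5. SA2 stands at 108.6 on the first component, and PA3 at 67.4 on the second.

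The number of features without a value on an array was larger at higher trait values. It averaged 1945 ± 123 (SD, n = 4), or 12.3% of features, in the lower pools and 2668 ± 514 (SD, n = 6), or 16.8%, in the higher pools. Its correlation with log2(trait value + 1) was r = 0.80 (permutation p = 0.0076) and rho = 0.78 (permutation p = 0.011), with an adjusted p of 0.091 over the 12 relations, which does not pass. Without PB5 and PD5, r was 0.78 (exact permutation p = 0.031). Within the 8 P pools, r was 0.79 (exact permutation p = 0.025) and rho was 0.90 (exact permutation p = 0.0046), and without PB5 and PD5 r was 0.72 (exact permutation p = 0.12). What made the authors leave a value empty is not given in the sources used here.

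**Figure D4:**
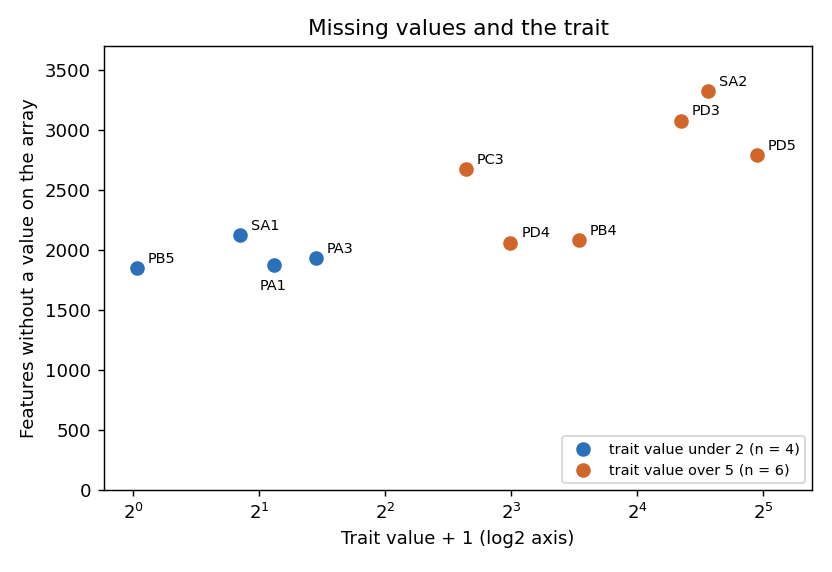
Features without a value on each array (y axis, of 15868) against trait value + 1 (x axis, log2 scale); each point is 1 pool, blue for trait values under 2 and orange for trait values over 5. The lower pools lay between 1851 and 2122, and the higher pools between 2063 (PD4) and 3321 (SA2).

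Many features differed between the pools and the reference. Of 12271 features, 3685 had a mean log ratio of at least 1 unit in size with an adjusted p under 0.05 (limma, test of the mean against 0), 1406 of them positive and 2279 negative. Of these 3685 features, 2721 had the same sign on every array with a value, 1057 positive and 1664 negative. With no minimum size, 8342 features passed in near even numbers, 4201 positive and 4141 negative. The highest means with the same sign throughout were those of feature 6675968_1, at 4.46 ± 1.78 (SD, n = 10, adjusted p = 3.6e-06), and 6667393_1, at 4.37 ± 1.05 (SD, n = 10, adjusted p = 1.4e-07). Both were highest in PB4 and lowest in PD4, where they were at 1.42 and 2.34. The lowest means were those of 6644798_1, at -5.16 ± 1.16 (SD, n = 10, adjusted p = 9.0e-08), and 6675545_1, at -4.22 ± 0.50 (SD, n = 10, adjusted p = 2.0e-09). Feature 6644798_1 was at -2.15 in SA2, its value nearest to 0. These tests leave out the spread of the reference, and no dye swap is named in the labels, so a dye effect is part of every such ratio.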

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

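Values below stood apart within their group of 4 to 6 pools, by a gap that exceeded Dixon's 95% limit. For values that are independent and not chosen for their spread, chance alone passes this limit in about 5% of groups. Here 9 of 51 passed, and 5 of the 9 were in SA2. The 51 groups come from the same arrays, and some hold features picked for their spread, so the 5% is no measure of chance here. The tests of SA2 by pools near it in trait value, by the S series, by its offset and by partner features were chosen after its position had been seen, and that by partner features after a first test of random error had been seen as well.

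SA2 had a score of 108.6 on the first component, against -0.95 for the nearest higher pool. Its median correlation with the other arrays was 0.56, against 0.75 for the next lowest higher pool. The lower pool PA3 was at 0.62, so a low correlation was not particular to SA2. The mean log ratio of SA2 was -0.35, the group of 235 features lay at -2.79 there, and feature 6644798_1 was at -2.15 against -4.68 for the nearest pool.

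The first test counted features over 2 units from the mean of the other pools. In SA2 81.55% of them lay below, where random error would give near even numbers. Over the other pools the share ran from 6.25% in SA1 to 89.26% in PD3, so an uneven share was not particular to SA2. After removal of the median offset of SA2, -0.42, its share was 56.5%, so the test could not part random error from an offset. This offset is the median difference of its features from the other pools. The median log ratio of the SA2 array itself, 0.047, lay within the 0.005 to 0.131 of all arrays. An offset does not account for the position of SA2 as a whole, since the gap on the first component was 0.863 of the range after the removal and 0.885 before. The trait value and the S series stay open: in deviations from the mean of the 9 other pools, where 0 is expected with nothing shared, SA2 correlated at 0.22 with PD5, at -0.044 with PD3 and at -0.012 with SA1, and the 9 correlations had an SD of 0.094. Random error of a weak array stays open, because the SA2 deviations of partner features, each the other's best match over the other 9 pools, correlated at 0.164, below the 0.227 to 0.512 of the other pools yet above the 0.0072 of shuffled partners. Random error together with a difference of this pool in expression may account for SA2 (partner correlation 0.164), and the values do not part these.

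Other values that stood apart were the following. PA3 had a score of 67.4 on the second component, against 7.72 for the nearest lower pool. In PB5 the group of 235 features was at -0.43, against 0.48 for the nearest lower pool, and feature 6676022_1 was at -2.22, against 2.38. Feature 6660349_1 was at 1.01 in PD5, against 0.54 for the nearest of the 4 higher pools with a value.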

How the results depend on the processing

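The absence of calls along the trait held in 22 of 23 alternatives and that between the groups in 20 of 21. The exception in both was array weights, with 3 and 13 calls, and with 1786 and 1917 features at an unadjusted p under 0.05; the cause was not tested. With the SD filter, which keeps the more variable features, these counts were 517 and 484. Fewer features were tested there, and whether this alone accounts for the smaller counts was not tested. Leaving out each pool in turn gave 741 (without PB5) to 1569 (without PD5) features at an unadjusted p under 0.05 along the trait, and 0 calls each time. The reference comparison gave 3282 to 3863 calls in all alternatives but that with no minimum size, 8342, which follows from its construction. The positive share of the 3685 calls was 38.2%, with 33.7% after median centring, 41.6% without SA2 and 50.4% with no minimum size, so the excess of negative calls depends on that minimum. The correlation of the first component with the trait ranged from 0.38 to 0.56 in size and passed in none of 15 alternatives. Where a pool was left out, the component was computed anew, so these values do not all describe the same axis. The rank correlation of the first component, the P pools alone and the omission of PB5 and PD5 are not among these 15. Their unadjusted permutation p-values were 0.025, 0.046 and 0.032. The correlation of missing values with the trait ranged from 0.69 to 0.87 in 14 alternatives chosen after the data were seen, with permutation p-values from 0.0051 to 0.025 before adjustment. The omission of PB5 and PD5 is not among these 14 and gave permutation p-values of 0.031 over all pools and 0.12 within the P pools. The median SD between pools ranged from 0.47 to 0.56. The random block and the P pools alone, also chosen after the data were seen, gave 0 calls. Of 236 alternatives of single features none changed direction, and 4, all with array weights, brought a feature past the threshold. These features were picked from the same arrays for a small p or a large mean, so a change of direction was unlikely from the start. The alternatives for gene lists and for single probes of a gene were not run, because no feature has a gene name. No paired analysis was possible because the replicate numbers only follow the order of accession. For the slope and the group difference, the recovery of added changes with 10 arrays sets what could be seen. For the other results no such recovery was run.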

Other observations

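The tests of SA2's share in the trait counts, of the S series and of the letters in pool names were chosen after the results they bear on had been seen, and the patterns of missing values were themselves first noticed in the data.

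PD3 and PD4 were the pair of pools whose deviations from the feature means correlated best, at 0.433, and PD3 also shared deviations with PC3 (0.32). With no shared deviation, -0.111 is expected if all pools vary equally, which SA2 did not. Over the 6 pairs of pools whose names share their leading 2 letters, the mean correlation was 0.034, against -0.119 over the other pairs (permutation test, one-sided p = 0.0368). Apart from PD3 and PD4, the same-letter pairs lay between -0.27 (SA1 and SA2) and 0.083 (PA3 and PA1). Centring on a mean that holds a pool as variable as SA2 tends to make the pairs of SA2 negative. In deviations from the mean of the 9 other pools, SA1 and SA2 correlated at -0.012. The value of -0.27 thus says little about that pair, although it enters the mean of 0.034. PD5 and SA1, whose letters differ, correlated at 0.20. As a hypothesis, pools with the same letters may share an origin such as a culture or a sort. The result rests on few pools: without PD4 the permutation p was 0.24, without PD3 it was 0.17, and without PA3, PB4, PB5 or PA1 it lay between 0.0555 and 0.0855. The labels do not say what the letters mean. All 3 PD pools are in the higher group and both PA pools in the lower group, so letters and trait are partly joined.

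More features reached an unadjusted p under 0.05 than the 5% that independent features would give, both along the trait (1184) and between the groups (1167). Chance was not excluded: 7 of 100 orderings of the trait values over the pools, the real one included, gave as many features, with a highest other count of 1640, and 5 of 100 drawn from the 210 splits into 4 and 6 pools did, with a highest other count of 1314. Whether SA2 alone accounts for the trait count stays open: the count was 1004 without it, and 17 of 100 orderings of the other 9 pools, the real one included, gave as many, with a highest other count of 1568. Without PB5 it was 741. Sets of features that vary together between pools, whatever the trait, may produce such counts; no biological explanation was tested.

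Features without a value were more numerous at higher trait values, and this held within the P pools (r = 0.7887), so the S series alone does not account for it. Within the P pools, the PA and PB arrays lacked 1851 (PB5) to 2081 (PB4) values. The PC and PD arrays lacked 2063 (PD4) to 3078 (PD3). All PA and PB pools but PB4 are in the lower group and all PC and PD pools in the higher group. Letters of the name and trait were thus not parted within the P pools. A lower level in the higher pools was tested as the source on the 1042 features missing more often from them. Where still measured, their median difference, higher minus lower, was 0.055 (95% bootstrap interval 0.019 to 0.10), against -0.14 for features on all arrays. A difference above -0.1 had been set beforehand to count against a lower level, but that bound was wrong, since values that remain are selected by the loss itself and may be the higher ones, so a lower level stays open. Features missing from 1 to 3 higher pools were missing from a lower pool 47.62 times as often as features present on all 6 higher pools (37.0% against 0.78%). Dim features lost on some arrays would give this, but so would any other property that makes a feature prone to loss. Signal intensities were not used, so the ratio does not single out dimness. It also leaves open why arrays of higher pools lost more features.

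A set of 79 features had a value on all 4 lower pools and on at most 1 higher pool. Only 2 of the 210 splits, the real one included, had as many, and 0 of 200 shuffles that kept the number of missing values of each array and each feature reached 79 (mean 44.4, highest 62), so array totals alone do not account for them. However, the split with the most such features, 153, parted PA1, PA3, PB4 and PB5 from the rest, and 38 of the 210 splits exceeded their own shuffles, although only 3, the real one included, did so by as much as the 34.6 features of the real split. PA1, PA3, PB4 and PB5 are all of the PA and PB pools, so the count was highest for a split by letters of the name, not by trait group. As 3 of these 4 pools are in the lower group, letters and trait are partly joined here as well. No test was run of why features lacked values. The opposite pattern, no value on the lower pools and a value on at least 5 higher pools, held for 10 features, with a median of 10 over the other splits.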
